A study of Mus musculus with 6 samples.

How the data were processed

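The series measured total RNA of whole mouse liver on 6 Affymetrix arrays, 3 of wild-type and 3 of Pfn2-/- animals of strain C57BL/6. Per the labels' protocols, livers were snap frozen, RNA was extracted with Trizol and labelled with biotin by the GeneChip WT PLUS kit. Per the submitters' processing notes, RMA and limma were used, and versions, probe set level and annotation are not given in the sources used here. The authors deposited log2 expression values, 1 per row and array, rounded to 2 decimals. RMA corrects background, quantile normalizes arrays to each other and summarises probes, which removes shifts that all genes share and compresses the fold changes of dim rows. The values ranged from 1.04 to 13.56. An array gives no read depth, and the number of arrays limits the precision.

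Rows were named from the platform annotation that came with the data. Of 34390 rows, 23521 had exactly 1 gene symbol, 1814 had several and 9055 were not listed and are unnamed here. Gene IDs of 23328 rows were in a reference gene table of GRCm38.p6, 0 of them with another symbol, and that table was used only for synonyms and the order of genes. Rows with exactly 1 symbol were tested, and where a gene had several rows the one with the highest mean over all 6 arrays was kept, blind to group, which left 22180 genes. Several rows existed for 1082 genes, of which 1 had rows that differed in sign at an unadjusted p under 0.05. No control rows could be identified among the rows, so the alternative that tests every row takes all 34390.

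Groups, lists, named genes, tests and alternatives were fixed before the data were examined, and those chosen afterwards are named in the closing section. The groups were compared with limma 3.58.1 in R 4.3.3, with genotype as the sole term, by lmFit and eBayes without trend and two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes. The prior degrees of freedom were 5.71 and the total 9.71. The unadjusted p under 0.01 served as a description. The 48 tested gene lists, each with at least 5 measured genes, covered iron and metals, actin, liver functions, the state of the samples and markers of cell types. Of 978 distinct list symbols 865 were matched, some through synonyms. Lists overlap, so they are not independent. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists, and its members were also adjusted over the list alone.

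Named genes were chosen by rule, with exceptions given in the closing section. They were the profilins, a fixed set of iron and actin genes, every list member past the threshold over its list alone and up to 4 members of smallest p per list described. The rule also took the 12 genes that moved most in each direction among those past the adjusted threshold with groups that do not overlap. Where a direction had fewer, it was filled with genes of smallest p that had an absolute log2 difference of 0.5 or more, groups that do not overlap and a higher-group mean above the median of all genes. That pool held 51 higher and 68 lower genes. A further 9 in each direction were predicted genes or other kinds that the rule does not use for filling.

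Genes near Pfn2 were taken as the nearest 30 on each side in the reference table, and their share at p under 0.01 was compared with that of all other genes by Fisher's exact test, two-sided. The fit was tested on simulated data made from the 22180 genes, with 200 genes changed in each of 10 runs. It called 71.2% of log2 changes of 1 and 97.1% of changes of 2, with 5.9 false calls per run on average, and 1% of unchanged genes had p under 0.01. The simulated genes varied independently and normally around each gene's own mean, with its residual SD. Genes of real arrays are correlated, so these shares need not hold for the measured arrays. With 200 genes changed at once the adjusted threshold is also easier to pass, so changes in fewer genes would be called less often. In the measured arrays 47 genes had an absolute log2 difference of 1 or more, and 0 genes passed.

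The alternatives were median centring, quantile normalization again, cyclic loess, filters on dim genes, other choices of rows per gene, eBayes with trend or robust, array weights, the replicate number as a block, and each array left out in turn. No sample was left out of the main comparisons.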

Results

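RNA was measured in whole liver of mice that lack profilin 2 (Pfn2-/-) and of wild-type mice, to find out how loss of Pfn2 alters liver gene expression. Profilin 2 is a small protein that binds monomeric actin and proteins that build actin filaments. The series holds 6 Affymetrix arrays of C57BL/6 animals, 3 per genotype, described as independent biological replicas. Replicates 1, 2 and 3 of either genotype were 9, 8.5 and 8 months old. Each array gave RMA expression values on the log2 scale for 34390 rows, with array medians of 4.36 to 4.41. The correlation between arrays across rows was 0.981 to 0.9898 within a genotype and 0.9815 to 0.9872 between genotypes, where rows are not independent replicates. The number of arrays limits the precision of every comparison. All differences below are knockout minus wild type on the log2 scale, from 3 arrays per group, with the standard error (SE) of the limma fit.

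The row of the targeted gene did not separate the genotypes. Pfn2 had log2 values of 4.02, 3.85 and 4.09 in wild-type liver and 3.88, 3.81 and 3.93 in the knockout, a difference of -0.11 (SE 0.12, 95% confidence interval -0.39 to 0.16, adjusted p = 0.961). The row was dim in both groups, since its mean of 3.93 lay at percentile 28.8 of all gene means and below their median of 4.72. Which part of the transcript its probes cover is not given in the sources used here, so the row cannot check the genotype labels. Of the other profilins, Pfn1, the abundant form in liver, had a mean of 8.82 ± 0.12 (SD) in wild type and 8.91 ± 0.21 in the knockout. The differences were 0.09 for Pfn1 (SE 0.14), 0.06 for Pfn3 (SE 0.17) and 0.06 for Pfn4 (SE 0.18), all smaller than their standard errors. The sign of all 3 turned when single arrays were left out, with ranges of -0.02 to 0.19, -0.12 to 0.19 and -0.11 to 0.21. Of the nearest 30 genes on each side of Pfn2, 19 were measured and 0 had an unadjusted p under 0.01 (smallest p = 0.1, Fisher's exact test against all other genes, two-sided, p = 1).

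Mme, Slc16a5 and Acot3 differed with the smallest p between the genotypes, but no gene passed the threshold over all genes in the main comparison. Mme, which encodes the membrane peptidase neprilysin and lies 32 tested genes from Pfn2 on the same chromosome, was 8.57-fold lower in the knockout (log2 difference -3.10, SE 0.36, 95% confidence interval -3.90 to -2.30). Slc16a5, of the monocarboxylate transporter family, was 4.32-fold lower (-2.11, SE 0.26), and Acot3, a peroxisomal acyl-CoA thioesterase, was 2.84-fold lower (-1.51, SE 0.19). These 3 genes shared the smallest adjusted p of 0.094. Mme passed with array weights, without knockout replicate 2 and with the replicate number as a block. Slc16a5 passed with array weights, without wild-type replicate 3 and with that block, and Acot3 passed without wild-type replicate 2. Among the 12 lower genes named by rule, the leptin receptor gene Lepr differed by -1.94 (SE 0.29), Nipal1 by -2.69 (SE 0.46) and the phosphatidate phosphatase gene Lpin1 by -2.00 (SE 0.34). Lepr and Nipal1 were dim in the knockout, at 3.99, 4.94 and 4.21 and at 4.17, 5.66 and 4.18, so the sizes of these 2 differences are not exact. The aspartate aminotransferase gene Got1 differed by -1.10 (SE 0.21), and Acot4, Snhg5, Asl, Plk3 and Sult1a1 differed by -1.02 to -0.62.

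Among the 12 higher genes, Ugt2b38, of the glucuronosyltransferase family, differed by 2.58 (SE 0.51). Its row was dim in wild type, at 4.44, 3.05 and 3.11 against lower quartiles of 3.51 to 3.57 over all rows of an array, so no exact fold is given, and it lay at 7.24, 5.07 and 6.02 in the knockout. Elovl3, a fatty acid elongase, differed by 1.41 (SE 0.29), Cyp7b1, an oxysterol hydroxylase, by 1.18 (SE 0.18), Dhrs9 by 1.04 (SE 0.15) and Adh6-ps1 by 1.26 (SE 0.23). The peroxisomal carnitine acyltransferase gene Crot differed by 0.72 (SE 0.15), and Osgin1, Slc22a28, Slc22a30, Enpp3, Adh4 and Pdilt by 0.61 to 0.91. All 24 genes had groups that did not overlap, which the rule required, and none passed the adjusted threshold in the main comparison. Beyond Mme, Slc16a5 and Acot3, Lepr and Adh6-ps1 passed without wild-type replicate 3, and Ugt2b38, Lepr and Nipal1 with the replicate block. Rows of the Ugt2b, Slc22a, Cyp, Mup, Saa and Adh families, and of Acot3 and Acot4, are uncertain because close paralogs can hybridise to the same probes.

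**Figure D1:**
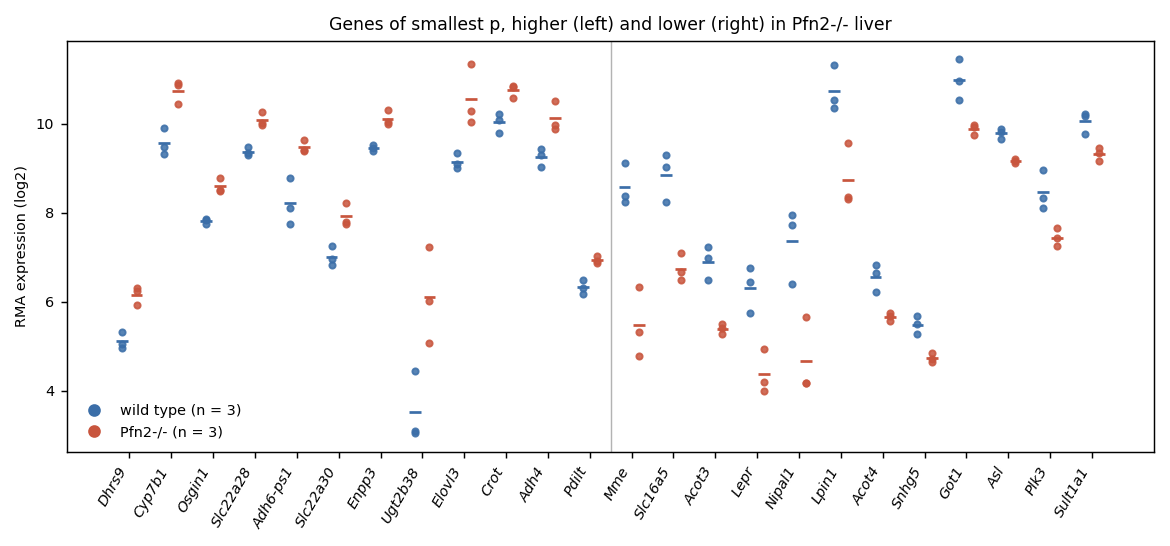
RMA expression (log2) of the 24 genes named by rule in each array, with 1 point per array (blue, wild type, and red, Pfn2-/-, 3 arrays each) and a bar at each group mean. The groups do not overlap in any of these genes, which the rule required, with Mme at 8.24 to 9.12 in wild type and 4.78 to 6.33 in the knockout.

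Across all 22180 genes tested with limma, 0 passed a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p under 0.01 there were 265 genes, 135 higher and 130 lower, where chance gives 222. At an unadjusted p under 0.05 there were 1174 genes, 593 higher and 581 lower, where chance gives 1109. The groups did not overlap in 9.9% of genes, where chance gives 10%. In the first principal component, which held 30.3% of the variance, wild-type arrays lay at -23.9 to 11.4 and knockout arrays at -10.7 to 21.4, so the genotypes overlapped. Single arrays moved these counts: without wild-type replicate 3 there were 6 genes past the adjusted threshold and 421 at p under 0.01, and without wild-type replicate 2 there were 1 and 148. Without knockout replicate 2 there were 3 past the adjusted threshold (Mme, Orm2 and Saa2) and without knockout replicate 3 there were 2, the clock gene Nr1d1 and Arrdc3. At p under 0.01 there were 168 without wild-type replicate 1 and 175 without knockout replicate 1. With the replicate number as a block 7 genes passed the adjusted threshold, and with array weights 2 did. Of 48 gene lists fixed before the data were examined, 20 passed camera with its preset correlation, 5 higher and 15 lower in the knockout, and 0 passed with an estimated correlation (smallest adjusted p = 0.419) or by fry (smallest adjusted p = 0.392). Adjusted over the list alone, 29 distinct list genes passed.

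Genes known to be expressed more in male liver had the smallest camera p among the lists and were higher in the knockout as a list (adjusted p = 4.49e-17, but adjusted p = 0.419 with an estimated correlation). Of 22 measured genes with higher expression in males, 11 rose in the knockout when adjusted over the list alone and 0 fell, and 0 passed over all genes. They included Moxd1, Ugt2b38, Elovl3, Hsd3b5 (1.36, SE 0.41), Cyp7b1 and Cyp2d9 (1.14, SE 0.40), while Selenbp2, Cyp4a12a, Cyp4a12b, Mup21 and Cyp2u1 rose by 0.58 to 0.81. Moxd1 was dim in 2 wild-type arrays, at 6.55, 3.36 and 3.26 against 8.14, 6.33 and 8.39 in the knockout, so the size of its difference is not exact. The list's median difference was 0.61, and its mean over genes, each centred on its own average, was -0.69 to -0.21 in the wild-type arrays and 0.14 to 0.56 in the knockout arrays. Without knockout replicate 1 the count past the list alone was 3, without wild-type replicate 2 it was 4, and with robust eBayes it was 7.

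Of 25 measured genes with higher expression in females, 6 fell and 2 rose when adjusted over the list alone. Those that fell were Cyp17a1, a steroid hydroxylase gene (-2.84, SE 0.65), the peroxisomal transporter gene Abcd2 (-2.55, SE 0.75), Fmo2 (-1.17, SE 0.26), Fmo4 (-0.93, SE 0.20), Nipal1 and Acot3. Abcd2 lay at 8.54, 9.03 and 6.98 in wild type and at 4.49, 7.58 and 4.84 in the knockout. Its groups overlapped and 2 knockout arrays were dim, so the size of its difference is not exact. Cyp3a44 rose by 0.49 (SE 0.13) and Cyp2c69 by 0.44 (SE 0.15). The median difference was -0.20 (camera adjusted p = 0.0302, adjusted p = 0.419 with an estimated correlation). Several members were dim in every array, such as Sult2a1 at 1.79 to 2.19 and Sult3a1 at 2.14 to 2.48, where a fall could hardly show. The camera call ended without wild-type replicate 2 (median -0.04, adjusted p = 0.207) and without knockout replicate 2 (median -0.05, 0.05). The median was -0.06 without knockout replicate 1 (0.0452), -0.46 with the filter at the lower quartile (0.00017) and -0.50 with the filter at the median (0.00137), and the count past the list alone was 5 without wild-type replicate 1 and with robust eBayes. The sex of the animals is not given in the sources used here. The Y-linked genes Eif2s3y, Kdm5d and Uty lay at 7.16 to 7.78, 6.19 to 6.67 and 6.97 to 7.38 over the 6 arrays, and Xist at 3.28 to 3.85. The sex chromosome list of 5 genes, with 0 past the list alone, had a camera adjusted p of 0.202.

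**Figure D2:**
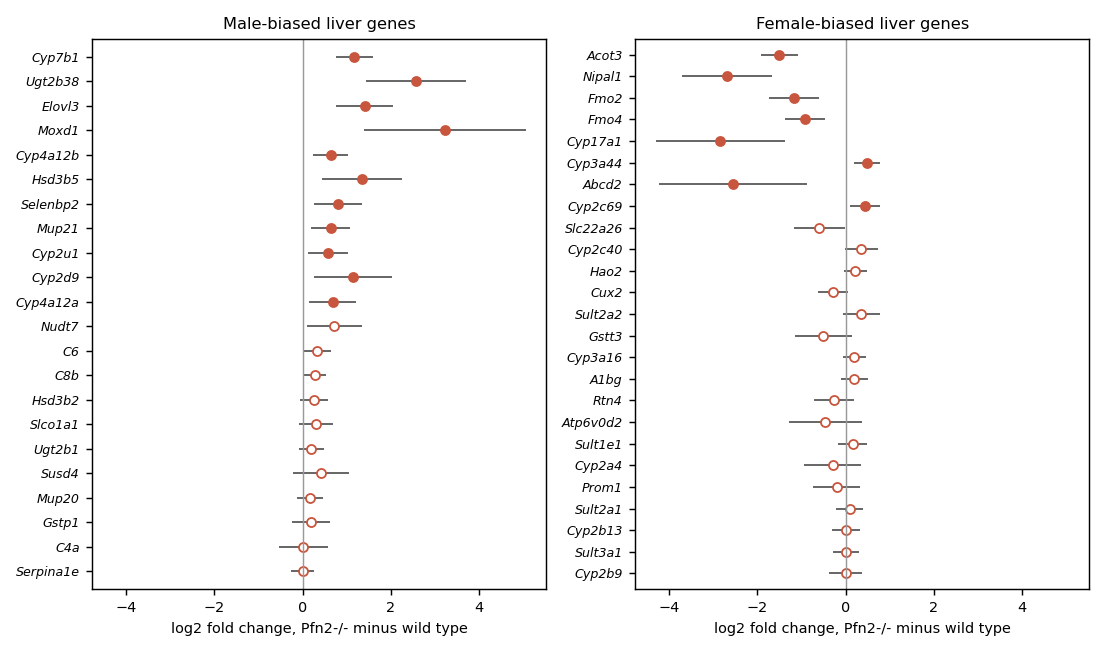
Log2 fold change (knockout minus wild type, x axis) of each measured male-biased (left) and female-biased (right) liver gene, with 95% confidence intervals from limma over 3 arrays per group. Filled points passed the adjusted threshold over the list alone, 11 of 22 on the left, all to the right of 0, and 8 of 25 on the right, 6 of them to the left of 0.

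No iron gene passed the test between the genotypes. Hamp, which encodes the iron hormone hepcidin, was at 12.42 ± 0.15 (SD) in wild type and 12.34 ± 0.23 in the knockout, a difference of -0.08 with a 95% confidence interval of -0.42 to 0.26. The transferrin receptor gene Tfrc differed by -0.30 (SE 0.24), the iron exporter gene Slc40a1 by -0.12 (SE 0.21), the ferritin gene Fth1 by 0.02 (SE 0.12), Tfr2 by 0.18 (SE 0.15) and Slc11a2 by -0.03 (SE 0.13). Hmox1, Aco1 and Ireb2 differed by -0.14 (SE 0.16), -0.07 (SE 0.13) and 0.17 (SE 0.20). The signs of Fth1, Slc11a2, Slc40a1, Hmox1 and Aco1 turned under other settings or without single arrays. In the BMP-SMAD pathway that sets hepcidin, Bmp6 differed by -0.36 (SE 0.16), Id1 by -0.37 (SE 0.15), Smad7 by -0.11 (SE 0.15) and Id2 by 0.49, none of them past the threshold adjusted over the list alone. Trf and Ftl1 were not analysed here, since they lie only in rows that name several genes.

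No member of the 6 iron and metal lists passed the threshold adjusted over its list alone, and none of these lists passed camera in the main comparison. Id2 did pass over its list with median centring, repeated quantile normalization, the filter at the median, eBayes with trend and array weights. Without wild-type replicate 3, Id2, Hamp2, Smad9, Epas1, Mt1 and Mt2 passed over their lists, and without knockout replicate 2, Lcn2 and Fgl1. Camera adjusted p was 0.202 for 11 mRNAs described with an iron-responsive element, Pfn2 among them, 0.826 for 24 genes of iron uptake, storage and export, and 0.218 for 26 genes of the hepcidin pathway. It was 0.523 for 17 genes of heme metabolism, 0.0959 for 17 genes of iron-sulfur cluster assembly (0.0251 without wild-type replicate 1, and 0.0357 and 0.0301 when every row was tested, with 1 symbol or in all) and 0.515 for 13 metallothionein, zinc and copper genes. For iron uptake the test and median (-0.01) lay below 0 and the mean (0.01) above it, and for the metallothionein list the test and median (0.11) lay above 0 and the mean (-0.09) below it.

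**Figure D3:**
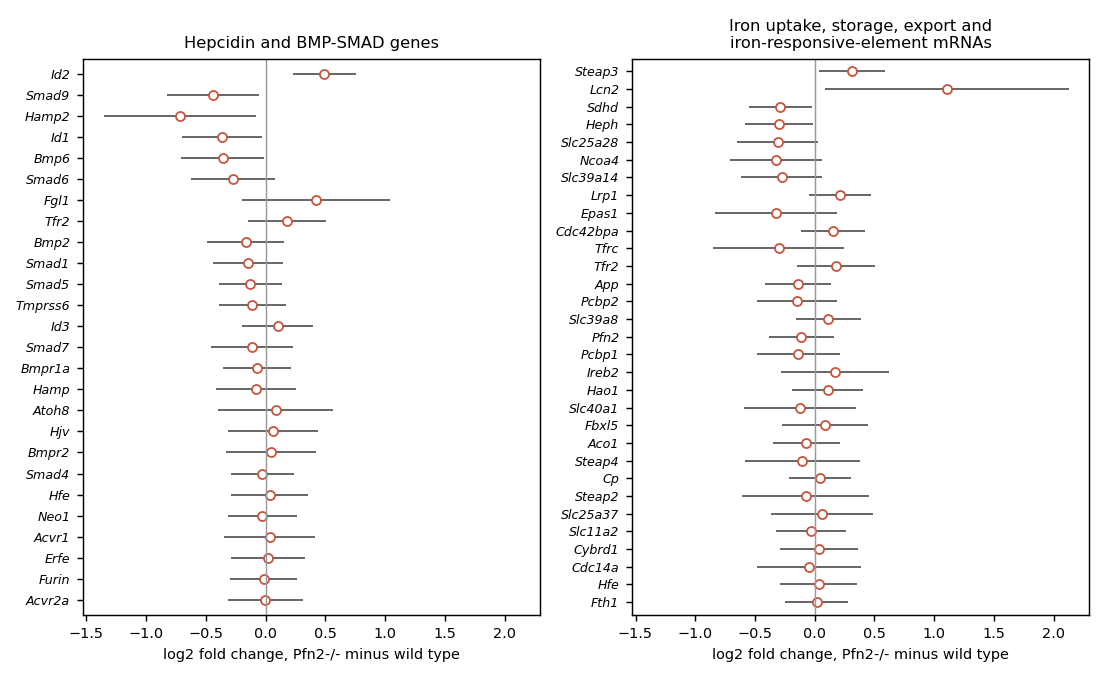
Log2 fold change (knockout minus wild type, x axis) with 95% confidence intervals from limma over 3 arrays per group for the hepcidin and BMP-SMAD genes (left) and the genes of iron uptake, storage, export and iron-responsive-element mRNAs (right). All points are open, since 0 passed the threshold over their list alone, and Hamp has an interval of -0.42 to 0.26.

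Among genes of the actin cytoskeleton, 1 listed target of serum response factor passed the test over its list. The actin gene Actb differed by -0.17 (SE 0.17) and the cofilin gene Cfl1 by 0.17 (SE 0.12). Among 38 profilin partners and actin nucleators and 33 genes of filament turnover, 0 passed over the list alone (camera adjusted p = 0.238 and 0.107). The first list passed camera without wild-type replicate 3 (0.0488) and the second without wild-type replicate 1 (0.0394). A list of 24 genes held targets of serum response factor, which responds to the pool of free actin, together with Srf, Mrtfa and Mrtfb. Of these 24 genes 1 rose over the list alone, the matricellular gene Ccn1 (0.68, SE 0.15). Acta2 differed by -0.53 and Ccn2 by -1.01 (camera adjusted p = 0.202 for the list). Ccn1 no longer passed over the list when either of wild-type replicates 1 and 2 or knockout replicates 1 and 3 was left out. With array weights Ccn2 passed beside it, and without wild-type replicate 3 Ccn2 and the filamin gene Flna did. The 31 genes of endocytosis and membrane traffic had 0 past the list alone (camera adjusted p = 0.979).

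Genes of fatty acid synthesis were lower in the knockout arrays by camera (adjusted p = 4.92e-08, but adjusted p = 0.419 with an estimated correlation), a call that ended without wild-type replicate 3. Those of cholesterol synthesis did not pass. Of 19 measured genes on the fatty acid synthesis list, 3 fell when adjusted over the list alone and 0 rose. They were the desaturase genes Fads1 (-0.43, SE 0.12) and Fads2 (-0.48, SE 0.14) and Lpin1. The last is a phosphatidate phosphatase gene and not an enzyme of fatty acid synthesis itself. Acly (-0.80, SE 0.53) and Fasn (-0.51, SE 0.59) did not pass over the list. Scd1 differed by -0.35 and Dgat2 by -0.34. The median was -0.49. Leaving out any of wild-type replicates 1, 2 and 3 or knockout replicates 1 and 3 ended the list calls of Fads1 and Fads2. This left 1 gene, Lpin1, or, without wild-type replicate 3, 2 genes, Lpin1 and Mlxipl. Mlxipl was higher in the knockout (0.32 in the main comparison). With eBayes trend 5 genes passed, Dgat2 and Scd1 among them. Wild-type replicate 3 stood apart, with Acly at 11.12 against 8.78 and 8.89 in the other wild-type arrays and Fasn at 11.84 against 9.12 and 9.41, and without it the median was -0.18 and the camera adjusted p 0.124. Without wild-type replicate 1 the median was -0.81 and without wild-type replicate 2 it was -0.79. The 19 cholesterol synthesis genes had 0 past the list alone and a median of -0.07 (camera adjusted p = 0.548). Their direction turned on single arrays, with a median of -0.31 without wild-type replicate 1 (0.00173), -0.22 without knockout replicate 1 (0.0228) and 0.22 without wild-type replicate 3 (0.00913).

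Of 22 genes of gluconeogenesis and glycolysis, 1 fell over the list alone, Igfbp1, a fasting-responsive binding protein gene (-2.11, SE 0.47), and the median was -0.15 (camera adjusted p = 0.02, adjusted p = 0.419 with an estimated correlation). The camera call ended without wild-type replicate 3 (0.0922), without knockout replicate 2 (median -0.09, 0.0752) and with the filter at the median (0.086). Igfbp1 no longer passed over the list without wild-type replicate 1 or 2, with robust eBayes or with the filter at the median. Genes past the list numbered 4 without wild-type replicate 3, 3 without knockout replicate 2, and 2 with array weights or without knockout replicate 3. Ppp1r3c, higher in the knockout (0.77 in the main comparison), was among them in each case except without knockout replicate 3. Of 27 genes of fatty acid oxidation 1 fell over the list alone, Acot3 (camera adjusted p = 0.336, and 0.0336 without wild-type replicate 2), with 2 genes past the list without knockout replicate 2 or 3. Of 22 genes of bile acid synthesis and transport 1 rose, Cyp7b1 (camera adjusted p = 0.116). There were 5 past the list without wild-type replicate 3, 4 with array weights and 2 with eBayes trend. Abcc4, lower in the knockout (-0.50 in the main comparison), was among the 5 and the 4. The list passed camera without wild-type replicate 3 (0.0467) and with the filters at the median (0.0291) and the lower quartile (0.0454).

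Among acute-phase genes, which hepatocytes express in inflammation, Saa2 and Orm2 had high values in 2 of the 3 knockout arrays. Saa2 lay at 6.76 to 7.80 in wild type and at 10.83, 7.31 and 12.22 in knockout replicates 1, 2 and 3, and Orm2 at 6.75 to 7.42 in wild type and at 9.58, 6.44 and 10.09. Saa3 and the haptoglobin gene Hp lay above wild type in all 3 knockout arrays, Saa3 at 6.69 to 8.18 against 6.07 to 6.16 and Hp, chosen after its values were seen, at 11.96 to 12.12 against 11.70 to 11.92. Knockout replicate 3, with the highest Saa2 and Orm2, also stood apart in the heat shock list (mean 0.67 against -0.18 to -0.02 in the other 5 arrays), with Hspa1b at 8.65 against 5.51 to 6.38 and Cdkn1a at 8.30 against 5.16 to 6.69. Of 23 genes 0 passed over the list alone, and the list's median was 0.12 (camera adjusted p = 0.00248, adjusted p = 0.469 with an estimated correlation). The call ended without knockout replicate 3 (median 0.06, adjusted p = 0.119) and without wild-type replicate 3 (median 0.04, 0.298), while without knockout replicate 2 the median was 0.25 and there were 5 genes past the list, of which Saa2 and Orm2 passed over all genes. Saa3 alone passed over the list without knockout replicate 3 and with the replicate block. Of 27 interferon-response genes 1 fell over the list alone, the GTPase gene Igtp (-0.98, SE 0.23), with a median of -0.11 (camera adjusted p = 0.00059, adjusted p = 0.419 with an estimated correlation). The camera call ended without knockout replicate 3 (median -0.06, 0.068), and without knockout replicate 2 the median was -0.18. Igtp no longer passed over the list with median centring, repeated quantile normalization, cyclic loess, either filter, every row tested or array weights, nor when any array except wild-type replicate 1 was left out.

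**Figure D4:**
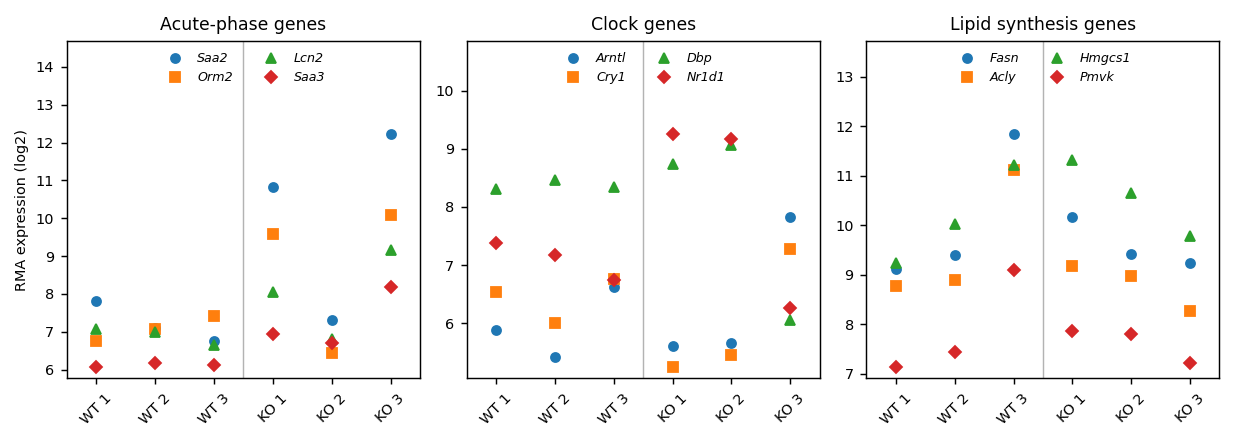
RMA expression (log2) of acute-phase (left), clock (middle) and lipid synthesis genes (right) in each of the 6 arrays (WT, wild type, and KO, Pfn2-/-), 1 marker per gene. Knockout replicates 1 and 3 carry the higher Saa2 values (10.83 and 12.22), knockout replicate 3 has Arntl at 7.82 and Dbp at 6.06, and wild-type replicate 3 has Fasn at 11.84.

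Markers of cell types and liver zones showed small shifts. Camera adjusted p was 0.00541 for 15 stellate cell and fibroblast markers (median -0.22), 0.0117 for 11 B and plasma cell markers (median -0.12) and 0.0225 for 17 endothelial markers (median -0.10), all lower in the knockout, each with adjusted p = 0.419 with an estimated correlation. These calls ended without knockout replicate 3 (0.0543, 0.0977 and 0.216 in the same order), the stellate call also without wild-type replicate 1 (median -0.13, 0.0692) and the B cell and endothelial calls without wild-type replicate 2 (0.128 and 0.151). The endothelial call ended too with repeated quantile normalization (0.05) and the filter at the median (0.0707). The stellate median was -0.13 without knockout replicate 2, the B cell median -0.28 when every row was tested, and the endothelial median -0.04 without knockout replicate 3 and -0.16 without wild-type replicate 3. Kupffer cell and macrophage markers (17 genes, median -0.12) had adjusted p = 0.0177 and adjusted p = 0.597 with an estimated correlation, and the median was 0.04 without wild-type replicate 2 (0.573). That call also ended without knockout replicate 3 (median -0.06, 0.0977) and with the filter at the median (0.134), and the median was -0.28 without wild-type replicate 3. Of 12 periportal markers 1 fell over the list alone, Asl, an enzyme of the urea cycle (-0.62, SE 0.12), while Ass1 differed by -0.49 and Arg1 by -0.32 (camera adjusted p = 0.0107, adjusted p = 0.469 with an estimated correlation). The periportal call ended without wild-type replicate 1 (0.0792), wild-type replicate 2 (median -0.07, 0.207) and knockout replicate 3 (0.0683). The periportal median, -0.12 in the main comparison, was -0.35 without wild-type replicate 3 and -0.19 without knockout replicate 2 or with array weights. Ass1 passed over the list with array weights, and Ass1 and Pck1 without wild-type replicate 3. Aldh1b1 (-0.22) was on both the periportal and the pericentral list. The 16 pericentral markers had a median of 0.15 (camera adjusted p = 0.0449, adjusted p = 0.58 with an estimated correlation). That call ended without wild-type replicate 1 (median 0.04, 0.504), knockout replicate 1 (median 0.08, 0.598) and knockout replicate 3 (0.0775), and with the other 3 choices of rows (0.0703 to 0.0914), and the median was 0.28 without knockout replicate 2. The other marker lists had 0 members past the list alone, with camera adjusted p of 0.523 for 14 hepatocyte, 0.189 for 16 T and NK cell, 0.548 for 15 monocyte and neutrophil, 0.561 for 8 adipocyte, 0.561 for 12 cholangiocyte and 0.561 for 12 pancreas genes. The T and NK cell list passed camera without wild-type replicate 3 (median -0.22, 0.00758). For the adipocyte and cholangiocyte lists the medians lay below 0 and the means and tests above it. The erythroid list had 4 measured genes, too few to test, with Car1 at 0.85.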

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

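The clock covariate and the window of the nearest tested genes were chosen after the data were seen, the other alternatives before. For named genes, 1102 of the values under alternatives kept direction and side of the adjusted threshold, 14 passed it newly and 15 turned in sign. For a part of the described lists, 356 values kept both, 32 were no longer past camera, 2 passed newly and 5 turned in sign. Camera calls gained or lost by the other lists are given with each list and are not in these counts. The cause of these changes was not tested unless named.

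The count at adjusted p under 0.05, 0 in the main comparison, was 2 with array weights (Mme and Slc16a5) and 0 to 6 when single arrays were left out, and stayed 0 under the scalings, filters, choices of rows, eBayes options and the clock covariate. Replicate numbers share an age between the genotypes. The correlation of their deviations was -0.08, 0.15 and 0.02, so apart from age the values gave no clear sign of pairs. Of the 6 arrays, 2 correlated best with their own number in the other genotype, which is what chance gives. With the replicate block, 7 genes passed (Ugt2b38, Cyp17a1, Lepr, Nipal1, Slc16a5, Cers6 and Mme) and 45 genes passed over the list alone. Among the 45 were Acta2 and Ccn2 beside Ccn1, 4 genes of gluconeogenesis and glycolysis and 2 clock genes. On the fatty acid synthesis list 1 gene, Lpin1, passed with that block. With the clock covariate Fads1, Fads2 and Igtp no longer passed over their lists.

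The 265 genes at p under 0.01 were 155 among genes above the median mean (fewer genes tested), 399 with array weights and 148 to 421 with single arrays left out. The 20 lists past camera became 0 with an estimated correlation, 0 by fry and 9 to 19 with arrays left out (9 without knockout replicate 3, 12 without wild-type replicate 2). The 29 genes past the list alone were 12 to 56 with arrays left out (12 without wild-type replicate 2 or knockout replicate 1, 56 without wild-type replicate 3). Male-biased genes past the list alone, 11 in the main comparison, were 7 with robust eBayes and 3 to 13 with arrays left out, and female-biased genes, 8, were 5 and 5 to 9. Among 10869 rows without a single symbol, 0 passed the adjusted threshold and 131 had p under 0.01. Genes near Pfn2 at p under 0.01, 0 otherwise, were 3 among the nearest 30 tested genes per side. Pfn2 stayed between -0.18 and -0.06 with arrays left out and was removed by the filter at the median.

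Signs turned for several values. Single arrays reversed the medians of 2 lists that passed camera, heat shock (0.23 in the main comparison) and Kupffer markers (-0.12), and the other values passed no test in the main comparison. Fth1 was -0.032 with quantile normalization and -0.025 with cyclic loess, and Slc11a2 0.013 with quantile normalization and 0.024 with array weights. The median of the iron uptake list was 0.017 with array weights. With arrays left out the ranges were -0.025 to 0.062 for Fth1, -0.117 to 0.033 for Slc11a2, -0.062 to 0.017 for the iron uptake list, -0.395 to 0.05 for Slc40a1, -0.292 to 0.008 for Hmox1, -0.12 to 0.005 for Aco1, -0.015 to 0.19 for Pfn1, -0.115 to 0.185 for Pfn3, -0.112 to 0.208 for Pfn4, -0.283 to 0.035 for Kupffer markers and -0.019 to 0.373 for heat shock. Dim rows such as Pfn2 lie close to the array's floor, where differences are compressed.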

Other observations

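The tests of sex, of Mme and of the clock genes in the knockout arrays were chosen after the result was seen, as were the wider windows around Pfn2 and the clock covariate. Genes outside the naming rule include Hp, Hspa1b, Cdkn1a, Acly, Fasn, Arntl, Dbp, Nr1d1 and Igf1. Several further gene groups were lower in the knockout by camera with its preset correlation, each with adjusted p = 0.419 with an estimated correlation. They were 25 cell cycle genes (median -0.14, adjusted p = 0.00248, with Ccnd1 at -0.97), 30 nuclear genes of oxidative phosphorylation (-0.09, 0.00272), 15 antigen presentation genes (-0.16, 0.00541) and 22 genes of fibrosis and matrix (-0.13, 0.00541), each with 0 members past the list alone. The cell cycle call ended without wild-type replicate 2 (median -0.09, 0.151; -0.24 without wild-type replicate 3), antigen presentation without wild-type replicate 2 (0.128) and without knockout replicate 3 (median -0.10, 0.0977), oxidative phosphorylation without knockout replicate 3 (0.0543) and fibrosis without wild-type replicate 1 (0.0505). Without wild-type replicate 3, Ccnd1 and Ccne1 of the cell cycle list and Ccn2 and Col5a2 of the fibrosis list passed over their lists. The 18 hypoxia genes (-0.13, 0.02) had 0 such members, and of 33 ribosomal protein genes (-0.07, 0.0344), both lists with adjusted p = 0.419 with an estimated correlation, 1 fell over the list alone, Rpl30 (-0.84, SE 0.18), a row that was dim in the knockout, at 3.37 to 3.93. The hypoxia call ended without wild-type replicate 1 (0.0633), wild-type replicate 2 (0.0778) and knockout replicate 1 (0.136), and the ribosomal call without wild-type replicate 2 (0.207), knockout replicate 2 (0.118) and knockout replicate 3 (0.068), both also with the filter at the median (0.113 and 0.177), and the ribosomal median was -0.10 without wild-type replicate 3. Rpl30 no longer passed over the list with that filter, with every row tested, or without any of wild-type replicates 2 and 3 and knockout replicates 1 and 3. The 23 genes of the unfolded protein response were higher (0.07, 0.0354, adjusted p = 0.419 with an estimated correlation) with 0 past the list alone, Sdf2l1, an ER chaperone partner, at 0.67. That call ended without wild-type replicate 3 (0.468) and knockout replicate 2 (median 0.03, 0.258), with array weights (0.142) and with every row tested (0.0542), and the median was 0.15, 0.12 and 0.19 without wild-type replicate 1, wild-type replicate 2 and knockout replicate 3. Over its list Sdf2l1 passed without wild-type replicate 1. The 12 heat shock genes were higher (0.23, 0.02, adjusted p = 0.531 with an estimated correlation) with a mean of 0.67 in knockout replicate 3 against -0.18 to -0.02 in the other 5 arrays, and the median was -0.019 without that array. That call also ended without wild-type replicate 1 (0.0633) and wild-type replicate 3 (0.085), with array weights (0.0853) and when every row was tested (median 0.11, with 0.0759 for rows with 1 symbol and 0.0964 for all), and the median was 0.37 without knockout replicate 1.

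Other lists did not pass camera. The catalytic glutathione synthesis gene Gclc rose over the list alone (0.50, SE 0.12) among 24 NRF2 and oxidative stress genes (camera adjusted p = 0.213), and the immediate early gene Jun fell over the list alone (-0.65, SE 0.15) among 20 (0.148). Gclc no longer passed over its list when any single array was left out, with cyclic loess, with the replicate block, with the clock covariate or when every row was tested. The same held for Jun with repeated quantile normalization, cyclic loess and every row tested, and without any 1 array except knockout replicate 3. The oxidative stress list passed camera without wild-type replicate 1 (0.0251). Among 13 growth hormone, STAT5 and IGF genes Igfbp1 fell over the list alone (0.202), with Socs2 at -0.99 (SE 0.46) and Igf1 at -0.16 (SE 0.11). The count was 0 without wild-type replicate 2 and with robust eBayes, and 4 without wild-type replicate 3. Bcl6, higher in the knockout (0.74 in the main comparison), was among the 4. The lists of 27 xenobiotic response genes (0.855), 13 p53 targets (0.121), 13 genes of mitochondrial stress (0.605), 6 substrain markers (0.157) and 20 clock genes (0.892) had 0 past the list alone. The clock count was 10 without knockout replicate 3, where Nr1d1 also passed over all genes, and 5 with the clock covariate, which is built from genes of this list. Of the xenobiotic response genes 4 passed over the list with array weights and 1, Cyp2b10, without wild-type replicate 3. The substrain marker Trim30d passed over its list without knockout replicate 2 and with the clock covariate. The p53 targets passed camera without knockout replicate 3 (0.0485) and the substrain markers without knockout replicate 2 (0.0378). For the xenobiotic list the median (0.01) lay above 0 and the mean (-0.03) and test below it, and for the clock list the median (-0.15) and test lay below 0 and the mean (0.01) above it.

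Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 0 genes at adjusted p under 0.05 (highest other 11), 265 at p under 0.01 (612), 20 lists past camera (13), 29 genes past the list alone (50), 0 genes near Pfn2 (1), 11 male-biased genes (4) and 8 female-biased genes (2). Wild-type replicates 1 and 2 with knockout replicate 2 against the remaining arrays gave the 612 and the 11, so a split that does not follow genotype called more genes than the genotype split.

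Of 22 male-biased genes 11 rose and of 25 female-biased genes 6 fell over the list alone, with 0 past all genes, the lists' camera calls lost with an estimated correlation (adjusted p = 0.419 for both), and the male-biased count at 3 without knockout replicate 1 and 4 without wild-type replicate 2. Animals of different sex in the groups are argued against, since the mean difference of the Y-linked genes Eif2s3y, Kdm5d and Uty was 0.06 and all 6 arrays expressed them. With each array's clock index as a covariate 12 male-biased genes passed over the list alone, but this covariate could not decide the question. The index was -0.63, -0.79 and 1.63 in the knockout, on both sides of -0.12, -0.32 and 0.23 in wild type. It thus differed little between the groups on average and could hardly take up a difference between them. A different time of day at collection still cannot be told apart from genotype. The index covers only part of the daily phase, and collection times are not given in the sources used here. An effect of the genotype may underlie the pattern, as a hypothesis, and hormone levels were not measured.

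In clock genes the knockout arrays lay outside the wild-type range, on both sides of it. The clock index (genes that peak around the end of the night minus genes that peak by day) was -0.12, -0.32 and 0.23 in wild-type replicates 1, 2 and 3 and -0.63, -0.79 and 1.63 in knockout replicates 1, 2 and 3. Nr1d1 lay at 9.25 and 9.16 in knockout replicates 1 and 2 and at 6.26 in knockout replicate 3, against 6.74 to 7.38 in wild type, and knockout replicate 3 had Arntl at 7.82 and Dbp at 6.06. That array also had raised heat shock genes (mean 0.67 against -0.18 to -0.02 in the other 5 arrays, with Hspa1b at 8.65 against 5.51 to 6.38) and Cdkn1a at 8.30 against 5.16 to 6.69. Other times of collection, another state or RNA quality of the samples and an effect of genotype on the clock all stay open, since the index is built from the genes that showed the pattern and collection times are not given in the sources used here.

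Mme, the gene with the smallest p, is a neighbour of Pfn2, 32 tested genes away on the same chromosome. A dim row is argued against, since its wild-type mean lay at percentile 95.1 of all genes. Alleles of another strain carried along with the targeted gene may contribute, as a hypothesis: among the nearest 30 tested genes on each side, which leave Mme out, 3 of 60 (Postn -0.73, Nbea -0.68 and P2ry1 -0.49, all lower) had p under 0.01, 5% against 1.2% elsewhere (Fisher's exact test, two-sided, p = 0.035). The planned window gave 0 of 19 measured genes (Fisher p = 1), and another split of the arrays gave 4 of the 60. Wider windows of 60, 100 and 150 per side, which include Mme, held 5 of 120 (p = 0.015, highest other split 4), 6 of 200 (p = 0.033, 5) and 7 of 300 (p = 0.096, 9), all lower, by Fisher's exact test, and with Mme left out 4 of 119 (p = 0.054, highest other split 4), 5 of 199 (p = 0.09, 5) and 6 of 299 (p = 0.17, 9), so linked alleles cannot be told apart from chance, and the origin of the targeted cells is not given in the sources used here.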
